A study of Mus musculus with 47 samples.

How the data were processed

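Polyadenylated RNA of cultured mouse microglia was sequenced after amplification with a low-input kit, per the labels' protocols. The 47 libraries fell into 10 groups of 5 genotypes with and without myelin, and each deposited column was matched to its sample by name. The authors deposited values in TPM, a transcript abundance scaled to a fixed total, for 53697 genes, and each column summed to 1000000 within rounding. Salmon 0.13.1, limma 3.40.6 and the mm10 genome build are named in the submitters' processing notes, which give no role for them. The annotation release and options are not given in the sources used here. Positions came from the GENCODE annotation of the same build, where 100% of the 10921 tested identifiers had one.

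TPM hold no read depth, so the depth of each library is unknown and no counting interval is given. The design written before the data were examined assumed gene counts and a count model. Since the values were TPM, limma on the log2 scale took its place. Gm23935, a non-coding RNA gene, and other non-coding genes took most of the TPM, so the nuclear protein-coding genes were rescaled to a total of 1000000 per library. Library factors came from a trimmed mean of log ratios, with 30% of ratios and 5% of levels trimmed at each end, and the result is called scaled TPM. Protein-coding and lincRNA genes with at least 5 scaled TPM in at least 4 libraries were tested, without mitochondrially encoded genes. These were 10921 genes, of which 10618 were coding and 303 lincRNA. Fold changes are on the scale of log2(scaled TPM + 1), which understates the change of low genes. A difference in total RNA per cell cannot be seen in values scaled this way.

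A model of limma 3.58.1 (R 4.3.3, the package data.table at 1.17.8) with a mean for each of the 10 groups was fitted to all libraries, with a weight per library from arrayWeights and a trend in the empirical Bayes step. Contrasts were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 16 comparisons were set before the data were examined, and 2 interactions of E3 and E4 with WT were added later. Apoe was compared with a two-sided exact permutation test of mean log2 levels. The 29 gene lists, of pathways, microglial states and markers of other cell types (655 entries), were also fixed beforehand. They were tested against the other genes with camera of limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Members were counted over all genes and adjusted over the list alone. In the lists called with the preset correlation, the median, the mean and the test had the same sign.

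The library weights were not part of the first plan. Once the unit was known, an unweighted fit was planned, with weights as an alternative. Weights were made the main choice after the coding shares of the libraries had been seen and before any test was run, to stand in for the depth weighting of a count model. They were kept after the counts of all fits had been seen side by side, and the choice raises most counts. In order of weighted fit, unweighted fit of 47 libraries and unweighted fit without the 4 Het libraries under 6% coding content, the counts were 2625, 1240 and 1875 in the mean myelin response, 1901, 25 and 699 in the E3 response, 2430, 329 and 1357 in the E4 response, 569, 13 and 254 in the KO response, 2891, 739 and 1918 in E4 against E3 untreated, 2970, 518 and 1257 in E4 against E3 after myelin. The choice was checked by dividing each of the 8 groups other than Het into a pair of parts, where no difference is due. Of 66 such splits, 37 had 0 calls with weights and the highest count was 622, 61 had 0 calls in the unweighted fit of 47 libraries with a highest count of 293, and 54 had 0 calls in the reduced unweighted fit with a highest count of 806. In these groups the weighted limma fit therefore makes false calls more often than the unweighted fit of 47 libraries. The Het groups went the other way. Of 10 splits of the untreated Het libraries, 7 had 0 calls with weights, 0 had 0 calls unweighted, and the highest counts were 6530 and 5761. Of 3 splits after myelin, 2 had 0 calls with weights and 0 unweighted. Counts from the unweighted fits are printed beside it for that reason. The weight estimate met its tolerance in the fit of all libraries, but stopped before it in some of the refits used as checks.

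The tests were tried on simulated values with known changes in 10921 genes. Of 100 genes changed 2-fold, 95% were recovered in a simulated E4 against E3 comparison, 93% in a WT myelin response and 92% in an interaction. At 1.5-fold the shares were 79%, 76% and 52%, with 11, 10 and 8 false calls. This simulation took the weights as the true noise, so it does not test them. Replicates of a group correlated between 0.788 and 0.989 on the log2 scale, and no pair was close enough to be 1 library under different names.

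Genes named in the text follow a rule fixed beforehand. It takes Apoe, up to 6 called genes per direction with the largest fold change and at least 5 scaled TPM, and up to 4 members per list with the smallest p. For comparisons of 2 groups the first kind also needs non-overlapping libraries. From the genes this rule takes, those with a known role were chosen for the text after their values were seen. Some genes this rule takes are not reported here. Alternatives fixed beforehand were median-of-ratios scaling, other filters on low values, a fit of only the groups compared, a replicate block, another pseudocount for Apoe, an estimated correlation and leaving out each library. Added after the data were seen were the unweighted fits, pseudocounts of 0.1 and 5, scaling to the coding total, a correction for GC content and length, and fits without the 4 Het libraries of low coding content or without both Het replicates numbered 2. Figures were drawn with matplotlib 3.10.9.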

Results

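RNA was sequenced from microglia, the resident macrophages of the brain, cultured from the forebrain of C57BL/6 mice of 5 genotypes. Wild-type (WT) cells were set beside cells carrying human APOE3 (E3) or APOE4 (E4) in place of mouse Apoe, 1 disrupted Apoe allele (Het) or none intact (KO). Apolipoprotein E carries cholesterol and other lipids between cells. Cultures were left untreated or given myelin, the lipid-rich sheath of axons, for 3 h and collected at 24 h. The 47 libraries made 10 groups of 4 or 5. The questions were how APOE4 differs from APOE3 at rest and after myelin, and how loss of Apoe alters the cells. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical in part.

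Apoe, at chromosome 7 from 19696109 to 19699188 in mm10 (ENSMUSG00000002985.16), was measured first because its level checks the labels. Untreated WT libraries held 56028 ± 6786 scaled TPM (SD, n = 5) and untreated KO libraries 74.6 ± 6.80 (SD, n = 5). The KO difference was -9.53 on the log2 scale (two-sided exact permutation p = 0.00794, the smallest the design allows). Untreated Het libraries held 47337 ± 21926 scaled TPM (SD, n = 5), a log2 difference from WT of -0.43 that did not exceed the spread (exact permutation p = 0.468). It was -0.02 without Het untreated replicate 5 and -0.15 without the Het libraries of low coding content described below. E3 and E4 libraries held 103 ± 10.8 (SD, n = 4) and 169.5 ± 35.9 (SD, n = 5), where reads of human APOE need not map to the mouse gene, so that these values are not the level of human APOE. The E4 value was higher by 0.70 (exact permutation p = 0.00794, the smallest the design allows).

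The non-coding RNA gene Gm23935 took between 69.4% and 99.0% of TPM in each library, so that nuclear protein-coding genes held 0.468% to 27.3%. Read depth is unknown in TPM, and this coding share stands as the measure of content at hand. It was 23.2 ± 2.54% in untreated WT, 13.6 ± 2.33% in E3, 12.1 ± 3.24% in E4, 10.7 ± 7.68% in Het and 20.8 ± 3.39% in KO libraries (SD, n = 4 to 5). After myelin it was 19.2 ± 4.43%, 15.6 ± 6.04%, 18.6 ± 3.39%, 7.25 ± 4.96% and 23.4 ± 1.59% in the same order. Coding genes held under 6% in 4 Het libraries, untreated replicates 3 and 5 and myelin replicates 1 and 2. Each count below is therefore followed by that of an unweighted fit without these 4 libraries, called the reduced fit. Counts of list members below are out of those measured, and the weighted fit tested 10921 genes in each comparison.

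**Figure D1:**
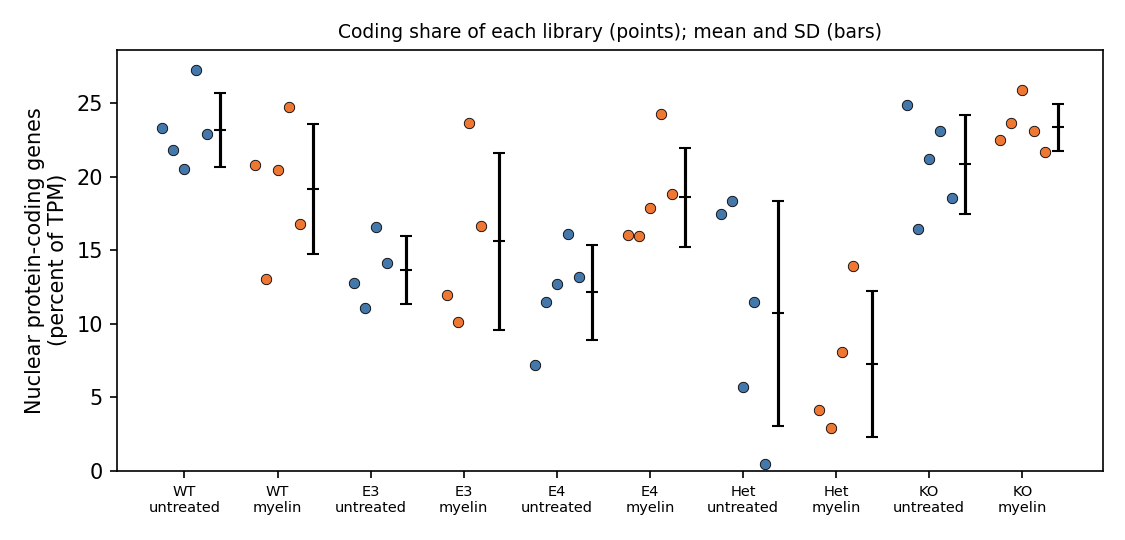
Percent of TPM on nuclear protein-coding genes (vertical axis) in each of the 47 libraries (points) by genotype and treatment, with mean and SD (bars). Values run from 0.468% to 27.3%, and the lowest is an untreated Het library.

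Averaged over the genotypes, myelin raised the exporter Abcg1 and lowered sterol synthesis transcripts, the latter not in KO. Abcg1, an exporter of cholesterol at chromosome 17 from 31057675 to 31117988 (ENSMUSG00000024030.6), rose by a log2 fold change of 1.27 ± 0.08 (log2 fold change ± SE here and below, limma adjusted p = 3.19e-15). Il18bp, which binds interleukin 18, rose by 0.91 ± 0.07, and Lcn2, an iron-sequestering acute phase protein, had a log2 fold change of -1.03 ± 0.10. Among genes of cholesterol biosynthesis and uptake, 21 of 23 fell, with 2 not called, and adjusted over the list alone 23 fell (adjusted p = 9.05e-20, adjusted p = 0.00439 with an estimated correlation). Fdps (-0.41 ± 0.04) and Srebf2 (the master regulator of sterol synthesis, -0.33 ± 0.04) were examples. Among lysosomal genes, 19 of 36 rose, with 17 not called, and adjusted over the list alone 23 rose (adjusted p = 4.75e-10, adjusted p = 0.166 with an estimated correlation). They included Atp6v0d2 (a proton pump subunit, 0.47 ± 0.06) and Psap (the sphingolipid activator precursor, 0.31 ± 0.05). Among inflammatory genes, 1 of 26 rose and 15 fell, with 10 not called, and adjusted over the list alone 2 rose and 19 fell (adjusted p = 1.88e-09, adjusted p = 0.0641 with an estimated correlation). Members included Il1b at -0.89 ± 0.08 and Ccl2 at -0.85 ± 0.08. In the antioxidant list 13 of 23 fell, with 10 not called, and adjusted over the list alone 1 rose and 15 fell (adjusted p = 1.09e-07, adjusted p = 0.0672 with an estimated correlation). A member was the cystine importer Slc7a11 (-0.56 ± 0.07). Markers of astrocytes moved with these groups, where 1 of 18 rose and 10 fell, with 7 not called, and adjusted over the list alone 1 rose and 13 fell (adjusted p = 1.37e-06, adjusted p = 0.137 with an estimated correlation). The list held Clu at -0.69 ± 0.08. Of markers of further cell types, 3 of 5 neuron markers fell, 6 of 16 fibroblast markers fell, 1 rose and 3 fell of 4 endothelial markers and 3 of 8 border macrophage markers fell (adjusted over the list alone 4 fell, 9 fell, 1 rose while 3 fell and 5 fell, adjusted p = 0.00509, 6.28e-04, 0.0309 and 0.00569, and adjusted p = 0.137, 0.431, 0.137 and 0.137 with an estimated correlation, in turn).

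Limma called 2625 genes changed (1346 higher, 1279 lower) in this mean, or 1119 higher and 1678 lower when scaled to the coding total. In the reduced fit limma called 1875 (1067 higher, 808 lower), 1766 of them in both fits. The 47 libraries without weights gave 1240. Leaving out 1 library at a time gave between 1108 genes without Het untreated replicate 1 and 3173 without Het untreated replicate 4.

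In E4 cells myelin raised Abcg1 by 2.33 ± 0.15 (adjusted p = 5.35e-15), from 7.89 ± 1.34 to 43.7 ± 4.95 scaled TPM (SD, n = 5 each). Reads on Apoe rose by 1.44 ± 0.16. Among lysosomal genes, 29 of 36 rose, with 7 not called, and adjusted over the list alone 31 rose (adjusted p = 1.65e-24, adjusted p = 0.0391 with an estimated correlation). Among its members were Atp6v0d2 (1.36 ± 0.11) and Psap (0.89 ± 0.09). Among sterol synthesis and uptake genes, 20 of 23 fell, with 3 not called, and adjusted over the list alone 20 fell (adjusted p = 8.93e-20, adjusted p = 0.00483 with an estimated correlation). It included Fdps at -0.81 ± 0.07. Among inflammatory genes, 18 of 26 fell, with 8 not called, and adjusted over the list alone 1 rose and 19 fell (adjusted p = 1.74e-12, adjusted p = 0.0175 with an estimated correlation), and Il1b (-1.50 ± 0.15), Ccl2 (-1.24 ± 0.15) and Lcn2 (-1.36 ± 0.19) were among them. In the stress response list 13 of 24 rose, with 11 not called, and adjusted over the list alone 13 rose (adjusted p = 2.53e-08, adjusted p = 0.0391 with an estimated correlation). A member was the asparagine synthetase Asns (0.81 ± 0.08). The 4 lists just given kept their calls with an estimated correlation.

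Further groups in E4 lost theirs. Among disease-associated microglia genes, 13 of 25 rose and 4 fell, with 8 not called, and adjusted over the list alone 15 rose and 4 fell (adjusted p = 3.61e-05, adjusted p = 0.161 with an estimated correlation). Examples were Gpnmb (1.17 ± 0.10) and Lgals3 (0.75 ± 0.07). Among targets of the sterol sensor LXR, 11 of 20 rose and 2 fell, with 7 not called, and adjusted over the list alone 12 rose and 3 fell (adjusted p = 5.96e-05, adjusted p = 0.119 with an estimated correlation). The list held the ubiquitin ligase Mylip (0.78 ± 0.08). For lipid storage, 8 of 21 rose and 3 fell, with 10 not called, and adjusted over the list alone 8 rose and 3 fell (adjusted p = 0.0170, adjusted p = 0.145 with an estimated correlation). Its members included the fatty acid binder Fabp4 at 1.04 ± 0.10 and the droplet coat protein Plin2 at 0.48 ± 0.06. Among interferon-stimulated genes, 14 of 28 fell, with 14 not called, and adjusted over the list alone 16 fell (adjusted p = 8.36e-07, adjusted p = 0.320 with an estimated correlation), Cxcl10 being at -1.63 ± 0.19. Beside these groups, 4 of 5 neuron, 1 of 16 fibroblast, 3 of 4 endothelial and 2 of 8 border macrophage markers fell (adjusted over the list alone 4, 0, 3 and 2 fell, adjusted p = 0.0287, 0.0435, 0.0108 and 0.00805, and adjusted p = 0.229, 0.686, 0.0572 and 0.161 with an estimated correlation, in turn), where limma had 3 of the fibroblast markers lower at an unadjusted p under 0.05. The mean log2 level of neuron markers was 4.12 ± 0.14 untreated and 3.77 ± 0.09 after myelin, and that of fibroblast and pericyte markers 5.04 ± 0.20 untreated and 4.74 ± 0.06 after myelin (SD, n = 5 each). In E4, 2430 genes changed (1323 higher, 1107 lower), or 1187 higher and 1495 lower when scaled to the coding total. The coding share also differed between these groups, at 12.1 ± 3.24% untreated and 18.6 ± 3.39% after myelin (SD, n = 5 each). The reduced fit called 1357 (810 higher, 547 lower), 1328 of them in both fits. The unweighted fit of 47 libraries called 329. Single removals gave between 1028 genes without E4 untreated replicate 3 and 3027 without E4 untreated replicate 5.

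E3 cells given myelin raised Abcg1 by 2.11 ± 0.16 (adjusted p = 2.55e-12), from 5.77 ± 0.455 to 28.9 ± 6.03 scaled TPM (SD, n = 4 each). In the lysosomal list, 25 of 36 rose, with 11 not called, and adjusted over the list alone 30 rose (adjusted p = 1.08e-16, adjusted p = 0.160 with an estimated correlation). Of these genes, Psap (0.73 ± 0.10) and Atp6v0d2 (0.82 ± 0.12) were examples. In the sterol list, 13 of 23 fell, with 10 not called, and adjusted over the list alone 14 fell (adjusted p = 7.26e-10, adjusted p = 0.160 with an estimated correlation). The list held Fdps (-0.72 ± 0.07) and Mvd (-0.65 ± 0.08). Among cytokine and NF-kB genes, 2 of 26 rose and 13 fell, with 11 not called, and adjusted over the list alone 2 rose and 14 fell (adjusted p = 7.25e-06, adjusted p = 0.161 with an estimated correlation). Single members were Il1b at -1.20 ± 0.16, Ccl2 at -1.06 ± 0.16 and, from the interferon list, Cxcl10 at -1.27 ± 0.21. Among LXR targets, 8 of 20 rose, with 12 not called, and adjusted over the list alone 10 rose (adjusted p = 1.50e-05, adjusted p = 0.160 with an estimated correlation). Genes of this list were Mylip (0.81 ± 0.08) and the exporter Abca1 (0.77 ± 0.11). Gpnmb (0.70 ± 0.10), Fabp4 (0.81 ± 0.11) and Plin2 (0.38 ± 0.07) also rose. Among respiratory chain genes, 1 of 31 rose and 6 fell, with 24 not called, and adjusted over the list alone 1 rose and 8 fell (adjusted p = 4.71e-04, adjusted p = 0.414 with an estimated correlation). Among genes of endosome and retromer trafficking 10 of 32 rose, with 22 not called, and adjusted over the list alone 13 rose (adjusted p = 0.00209, adjusted p = 0.414 with an estimated correlation). Markers of other cells moved with these groups, where 1 of 16 fibroblast, 3 of 4 endothelial and 2 of 8 border macrophage markers fell (adjusted over the list alone 0, 3 and 4 fell, adjusted p = 0.00518, 0.0417 and 0.0175, and adjusted p = 0.470, 0.161 and 0.271 with an estimated correlation, in turn), where limma had 5 of the fibroblast markers lower at an unadjusted p under 0.05. The mean log2 level of fibroblast and pericyte markers was 5.99 ± 0.18 untreated and 5.44 ± 0.17 after myelin, and that of endothelial markers 3.11 ± 0.05 untreated and 2.65 ± 0.08 after myelin (SD, n = 4 each). In E3, 1901 genes changed (1075 higher, 826 lower), and the list calls were lost with an estimated correlation. Without weights or those 4 libraries limma called 699 (438 higher, 261 lower), 680 of them in both fits. Unweighted, the 47 libraries gave 25. Leaving out single libraries gave between 578 genes without E3 myelin replicate 4 and 2416 without E3 myelin replicate 2.

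The E3 and E4 responses shared 586 risen and 324 fallen genes, where independent lists would share 130.2 and 83.7, and 5 of the 915 genes called in both went opposite ways. The difference between the responses was tested as an interaction. The glutathione-degrading enzyme Chac1 (0.69 ± 0.15) and Asns (0.64 ± 0.12) responded more in E4, and the Notch target Hes5 (-1.15 ± 0.27) was lower. In the stress list 3 of 24 rose, with 21 not called, and adjusted over the list alone 8 rose (adjusted p = 5.79e-07, adjusted p = 0.229 with an estimated correlation). Limma called 40 genes changed (19 higher, 21 lower), but the reduced fit called 0, with 469 genes at an unadjusted p under 0.05 against 1340 in the weighted limma fit. The unweighted fit of 47 libraries called 0 too, with 143 at that p, and scaling to the coding total gave 6 higher and 27 lower. The interaction thus did not hold up, and single libraries moved its count between 1 gene without E3 myelin replicate 4 and 84 without E3 myelin replicate 2.

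WT cells held 5.99 ± 0.417 scaled TPM of Abcg1 untreated and 7.47 ± 1.33 after myelin (SD, n = 5 each). Scand1 (2.07 ± 0.27), a SCAN domain protein, and Mcat (1.08 ± 0.17), of mitochondrial fatty acid synthesis, rose. Mmp13 (-0.74 ± 0.17), Ereg (-0.62 ± 0.14), Pf4 (-0.59 ± 0.12) and the neutrophil attractant Cxcl1 (-0.59 ± 0.18) fell. Among border macrophage and monocyte markers, 3 of 8 fell, with 5 not called, and adjusted over the list alone 4 fell (adjusted p = 0.0367, adjusted p = 0.966 with an estimated correlation). Among the sterol list, 1 of 23 rose and 1 fell, with 21 not called, and adjusted over the list alone 1 rose and 1 fell (adjusted p = 0.00711, adjusted p = 0.966 with an estimated correlation). In WT, 1074 genes changed (974 higher, 100 lower). The reduced count was 744 (690 higher, 54 lower), 727 of them in both fits. The 47 libraries without weights gave 419. With 1 library left out limma called between 857 genes without WT myelin replicate 5 and 2392 without WT myelin replicate 4, the latter 1431 higher and 961 lower.

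Against WT, the response of Abcg1 was larger by 1.85 ± 0.24 in E3 and 2.08 ± 0.23 in E4, also called by the reduced fit (adjusted p = 0.00369 and 4.08e-05). Psap (0.75 ± 0.15 and 0.91 ± 0.14) and Gpnmb (0.87 ± 0.15 and 1.33 ± 0.15) also responded more in E3 and E4 in turn, and Fdps responded with a difference of -0.56 ± 0.11 and -0.65 ± 0.10. In E4 Atp6v0d2 had a difference of 1.53 ± 0.17. Of lysosomal genes in E4, 19 of 36 rose, with 17 not called, and adjusted over the list alone 30 rose (adjusted p = 1.07e-21, adjusted p = 0.0891 with an estimated correlation). In E3, 14 of 36 rose, with 22 not called, and adjusted over the list alone 19 rose (adjusted p = 2.09e-12, adjusted p = 0.358 with an estimated correlation). Of other cells in E3, 0 of 16 fibroblast and 1 of 4 endothelial markers fell (adjusted over the list alone 0 and 3 fell, adjusted p = 0.00909 and 0.0490, and adjusted p = 0.612 and 0.358 with an estimated correlation, in turn), where limma had 3 of the fibroblast markers lower at an unadjusted p under 0.05. In E4, 0 of 16 fibroblast and 2 of 4 endothelial markers fell (adjusted over the list alone 0 and 4 fell, adjusted p = 0.0163 and 0.00475, and adjusted p = 0.659 and 0.0891 with an estimated correlation, in turn), where limma had 3 of the fibroblast markers lower at an unadjusted p under 0.05. These interactions were added after the data were seen. For E3, 1046 genes changed (521 higher, 525 lower). In the reduced fit limma called 233 (146 higher, 87 lower), 227 of them in both fits. The unweighted fit of 47 libraries called 1. For E4, 972 genes changed (392 higher, 580 lower). The reduced fit called 505 (266 higher, 239 lower), 482 of them in both fits. Unweighted, the 47 libraries gave 9. Without WT myelin replicate 4 these counts were 2448 and 2210.

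**Figure D2:**
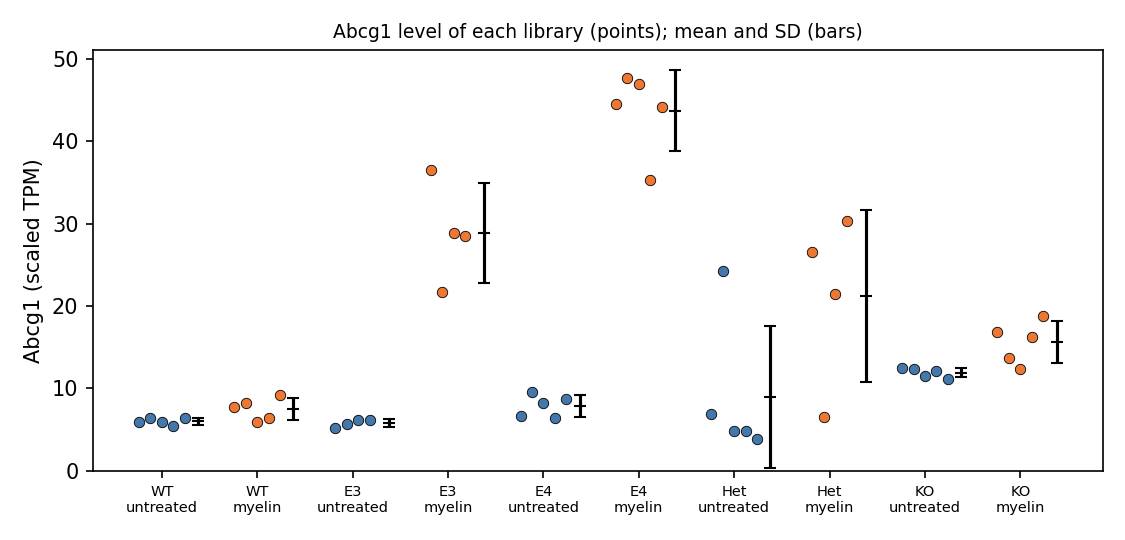
Abcg1 level in scaled TPM (vertical axis) of each of the 47 libraries (points) by genotype and treatment, with mean and SD (bars). Group means were 28.9 in E3 and 43.7 in E4 after myelin and 7.47 in WT after myelin, and replicate 2 of Het stood at 24.3 untreated and 6.49 after myelin.

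KO cells given myelin lowered antioxidant transcripts, and 10 of 23 fell, with 13 not called, and adjusted over the list alone 20 fell (adjusted p = 1.81e-17, adjusted p = 0.00194 with an estimated correlation). Of the list calls in KO, this 1 held with an estimated correlation. Srxn1 (a sulfiredoxin, -0.65 ± 0.09) and Pgd (of the pentose phosphate pathway, -0.51 ± 0.07) were in it, and Lcn2 stood at -1.45 ± 0.19. Among cell cycle genes, 7 of 32 rose, with 25 not called, and adjusted over the list alone 16 rose (adjusted p = 7.02e-12, adjusted p = 0.0911 with an estimated correlation). Named members were the helicase subunits Mcm6 (0.47 ± 0.07) and Mcm2 (0.48 ± 0.09). Among stress response genes, 8 of 24 rose, with 16 not called, and adjusted over the list alone 11 rose (adjusted p = 9.49e-07, adjusted p = 0.0873 with an estimated correlation). It included Asns at 0.50 ± 0.09. Among immediate early genes, 7 of 19 fell, with 12 not called, and adjusted over the list alone 7 fell (adjusted p = 5.19e-06, adjusted p = 0.0911 with an estimated correlation). A member was Fosb at -0.99 ± 0.17. The microglial receptor Gpr34 rose (0.89 ± 0.18). Among astrocyte markers, 9 of 18 fell, with 9 not called, and adjusted over the list alone 12 fell (adjusted p = 6.72e-12, adjusted p = 0.0535 with an estimated correlation). The list held Clu at -0.89 ± 0.16. Among neuron markers 2 of 5 fell, with 3 not called, and adjusted over the list alone 4 fell (adjusted p = 1.84e-04, adjusted p = 0.0535 with an estimated correlation). In KO, 569 genes changed (263 higher, 306 lower), a balance that turned to 244 higher and 175 lower when only these groups were fitted, to 285 higher and 227 lower with a pseudocount of 5 and to 333 higher and 294 lower without KO myelin replicate 4. Without weights or those 4 libraries limma called 254 (110 higher, 144 lower), 253 of them in both fits. The 47 libraries without weights gave 13. Single libraries moved the count between 335 genes without KO untreated replicate 3 and 657 without KO untreated replicate 4.

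The response differed from that of WT for Mcm6 (0.51 ± 0.11), the purinergic receptor P2ry12 (1.10 ± 0.28) and the chaperone Hsp90b1 (0.44 ± 0.10), which were higher, and for Scand1 (-2.20 ± 0.36) and Srxn1 (-0.56 ± 0.14). Among the antioxidant list, 5 of 23 fell, with 18 not called, and adjusted over the list alone 6 fell (adjusted p = 4.01e-04, adjusted p = 0.468 with an estimated correlation). Among cell cycle genes 4 of 32 rose, with 28 not called, and adjusted over the list alone 4 rose (adjusted p = 3.04e-04, adjusted p = 0.468 with an estimated correlation). Of other cells, 2 of 18 astrocyte markers fell (adjusted over the list alone 7 fell, adjusted p = 8.36e-04, and adjusted p = 0.468 with an estimated correlation). In this interaction 1142 genes changed (360 higher, 782 lower). The reduced count was 385 (98 higher, 287 lower), 382 of them in both fits. The unweighted fit of 47 libraries called 10. Single removals gave between 819 genes without WT untreated replicate 5 and 2379 without WT myelin replicate 4, the latter 1136 higher and 1243 lower.

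Het libraries gave 8.91 ± 8.65 scaled TPM of Abcg1 untreated (SD, n = 5) and 21.2 ± 10.5 after myelin (SD, n = 4), with replicate 2 at 24.3 untreated and 6.49 after myelin. Clu (-1.50 ± 0.25) fell and the interferon-induced Ifit3 (1.81 ± 0.44) rose. In the interferon list 12 of 28 rose, with 16 not called, and adjusted over the list alone 21 rose (adjusted p = 3.35e-15, adjusted p = 0.181 with an estimated correlation). Without Het myelin replicate 1 the median of this list was -0.17, against 0.87 with all libraries. In the sterol list 14 of 23 fell, with 9 not called, and adjusted over the list alone 16 fell (adjusted p = 3.71e-12, adjusted p = 0.0738 with an estimated correlation). For ribosomal proteins, 8 of 38 rose, with 30 not called, and adjusted over the list alone 35 rose (adjusted p = 2.77e-18, adjusted p = 0.263 with an estimated correlation). Beside these, 8 of 18 astrocyte and 4 of 16 fibroblast markers fell (adjusted over the list alone 12 and 4 fell, adjusted p = 1.70e-08 and 4.66e-04, and adjusted p = 0.181 and 0.488 with an estimated correlation, in turn), and without Het myelin replicate 1 the median of the latter was 0.08. Mitochondrially encoded genes held 2.84 ± 0.805% of coding TPM in untreated Het libraries (SD, n = 5) and 6.21 ± 4.54% after myelin (SD, n = 4), with 12.8% in myelin replicate 2. In Het, 653 genes changed (171 higher, 482 lower). The balance turned to 93 higher and 11 lower with no filter on low values, with 4 genes shared, and to 74 higher and 62 lower in the unweighted fit of 47 libraries. The reduced fit called 2, both shared. The calls thus did not hold up in that fit, but it keeps few Het libraries, untreated replicate 2 among them, and cannot decide. Without both Het replicates numbered 2, limma called 565 genes, 349 of them also called with all libraries. Leaving out 1 library gave between 0 genes without Het untreated replicate 1 and 3021 without Het untreated replicate 4. At an unadjusted p under 0.05 limma called 301 genes without Het untreated replicate 1.

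Untreated E4 cells differed from untreated E3 cells in glial, inflammatory and proliferation genes. Hes5 was higher by 2.75 ± 0.20 (adjusted p = 1.13e-13), as were the acute phase gene Serpina3n (2.13 ± 0.18) and the astrocytic neurotensin receptor Ntsr2 (1.99 ± 0.29). The thyroxine carrier Ttr (-3.15 ± 0.81) and the growth factor Igf2 (-2.32 ± 0.48) were lower. Ttr scattered, at 32.8 to 152 scaled TPM in untreated E3, 0.239 to 113 in E3 after myelin and 0.126 to 23.1 in untreated E4. Among inflammatory genes, 16 of 26 rose and 1 fell, with 9 not called, and adjusted over the list alone 16 rose and 3 fell (adjusted p = 2.77e-09, adjusted p = 0.0669 with an estimated correlation). Members included Tnf (1.39 ± 0.11), Il1b (1.43 ± 0.16) and Nfkbia (an NF-kB inhibitor, 1.05 ± 0.09). Among immediate early genes, 11 of 19 rose and 2 fell, with 6 not called, and adjusted over the list alone 12 rose and 2 fell (adjusted p = 5.15e-08, adjusted p = 0.0669 with an estimated correlation). Among its members were Nr4a1 (1.27 ± 0.12) and Fos (0.98 ± 0.11). Among cell cycle genes, 28 of 32 fell, with 4 not called, and adjusted over the list alone 28 fell (adjusted p = 5.73e-14, adjusted p = 0.0685 with an estimated correlation). Examples were Rrm2 at -1.25 ± 0.15 and Cdk1 at -0.72 ± 0.11. Among astrocyte markers beside them, 15 of 18 rose, with 3 not called, and adjusted over the list alone 16 rose (adjusted p = 3.68e-12, adjusted p = 0.0669 with an estimated correlation). Its members included Sox9 (1.34 ± 0.15) and Aldoc (1.30 ± 0.18). Among fibroblast and pericyte markers, 12 of 16 fell, with 4 not called, and adjusted over the list alone 13 fell (adjusted p = 4.55e-08, adjusted p = 0.193 with an estimated correlation). Of these genes, Bgn at -1.68 ± 0.21 and Pdgfrb at -0.92 ± 0.15 were examples.

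Among complement genes, 7 of 12 rose, with 5 not called, and adjusted over the list alone 9 rose (adjusted p = 1.35e-04, adjusted p = 0.0805 with an estimated correlation). The list held C4b (1.82 ± 0.24) and C1qa (0.55 ± 0.10). Among LXR targets, 9 of 20 rose, with 11 not called, and adjusted over the list alone 13 rose (adjusted p = 4.45e-05, adjusted p = 0.0805 with an estimated correlation). Single members were Cd5l at 1.22 ± 0.15 and the LXR gene Nr1h3 at 0.63 ± 0.09. Among homeostatic microglia genes, 10 of 23 rose, with 13 not called, and adjusted over the list alone 13 rose (adjusted p = 7.32e-05, adjusted p = 0.0805 with an estimated correlation). Among oligodendrocyte markers 4 of 5 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.0317, adjusted p = 0.0805 with an estimated correlation). Among genes of class I antigen presentation 8 of 17 rose, with 9 not called, and adjusted over the list alone 10 rose and 1 fell (adjusted p = 0.00525, adjusted p = 0.283 with an estimated correlation). As to further cell types, 2 of 4 endothelial markers fell (adjusted over the list alone 1 rose while 3 fell, adjusted p = 0.0346, and adjusted p = 0.0854 with an estimated correlation). Limma called 2891 genes changed (1545 higher, 1346 lower), and the list calls were lost with an estimated correlation. In the reduced fit limma called 1918 (981 higher, 937 lower), 1892 of them in both fits. Unweighted, the 47 libraries gave 739. Leaving out single libraries gave between 2364 genes without E4 untreated replicate 3 and 2893 without E4 untreated replicate 1.

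After myelin, E4 was above E3 for Ntsr2 (2.32 ± 0.27), Serpina3n (1.87 ± 0.16) and reads on Apoe (1.67 ± 0.16). Igf2 (-2.28 ± 0.44) was lower. Among cytokine genes, 13 of 26 rose and 4 fell, with 9 not called, and adjusted over the list alone 14 rose and 4 fell (adjusted p = 5.97e-05, adjusted p = 0.211 with an estimated correlation). Genes of this list were Tnf (1.39 ± 0.10), Il1a (1.23 ± 0.15) and Nfkbia (0.91 ± 0.08), and Egr1 of the immediate early list was at 1.58 ± 0.17. Of cell cycle genes, 18 of 32 fell, with 14 not called, and adjusted over the list alone 22 fell (adjusted p = 8.19e-09, adjusted p = 0.211 with an estimated correlation). It included Rrm2 at -1.14 ± 0.14. Among class II antigen presentation genes, 3 of 5 rose, with 2 not called, and adjusted over the list alone 3 rose (adjusted p = 0.0237, adjusted p = 0.211 with an estimated correlation). A member was the invariant chain Cd74 at 0.73 ± 0.11. Among astrocyte markers, 16 of 18 rose, with 2 not called, and adjusted over the list alone 16 rose (adjusted p = 5.70e-13, adjusted p = 0.0511 with an estimated correlation). Among fibroblast markers 12 of 16 fell, with 4 not called, and adjusted over the list alone 13 fell (adjusted p = 4.03e-07, adjusted p = 0.255 with an estimated correlation), Bgn being at -1.54 ± 0.19. Also, 3 of 4 endothelial markers fell (adjusted over the list alone 3 fell, adjusted p = 0.00195, and adjusted p = 0.0511 with an estimated correlation). Limma called 2970 genes changed (1681 higher, 1289 lower), or 1242 higher and 1501 lower when scaled to the coding total. The reduced fit called 1257 (727 higher, 530 lower), 1238 of them in both fits. The 47 libraries without weights gave 518. With 1 library left out limma called between 1151 genes without E3 myelin replicate 4 and 3410 without E3 myelin replicate 2. Of the genes called in both states, 845 were higher and 771 lower in E4 each time, where independent lists would share 238 and 159.

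Untreated KO libraries lay far from WT. Apart from Apoe (-9.59 ± 0.16), the glutathione synthesis subunit Gclm (4.12 ± 0.23), Tmem160 (4.27 ± 0.16, within 10.0 Mb of Apoe) and the lipoprotein lipase Lpl (1.97 ± 0.11) were higher in KO. Among fibroblast and pericyte markers, 15 of 16 fell, with 1 not called, and adjusted over the list alone 15 fell (adjusted p = 1.40e-09, adjusted p = 0.325 with an estimated correlation). Named members were Pdgfrb (-3.20 ± 0.14), Fn1 (-3.04 ± 0.17) and Bgn (-3.65 ± 0.19). Among cell cycle genes, 1 of 32 rose and 30 fell, with 1 not called, and adjusted over the list alone 1 rose and 30 fell (adjusted p = 1.75e-11, adjusted p = 0.258 with an estimated correlation). The list held Rrm2 at -2.24 ± 0.14. Among inflammatory genes, 2 of 26 rose and 22 fell, with 2 not called, and adjusted over the list alone 2 rose and 22 fell (adjusted p = 9.96e-07, adjusted p = 0.258 with an estimated correlation). Members included Il1a (-3.17 ± 0.15), Ptgs2 (-3.63 ± 0.17) and Il6 (-3.64 ± 0.21). Among lysosomal genes, 30 of 36 rose and 1 fell, with 5 not called, and adjusted over the list alone 30 rose and 1 fell (adjusted p = 3.27e-06, adjusted p = 0.540 with an estimated correlation). Among its members were Lamp1 at 2.82 ± 0.20 and the acid lipase Lipa at 1.13 ± 0.08. The antioxidant list was mixed, where 13 of 23 rose and 4 fell, with 6 not called, and adjusted over the list alone 13 rose and 4 fell (adjusted p = 0.0272, adjusted p = 0.540 with an estimated correlation). It included Nqo1 at -3.09 ± 0.18. Among glycolysis genes 3 of 24 rose and 18 fell, with 3 not called, and adjusted over the list alone 4 rose and 19 fell (adjusted p = 0.00162, adjusted p = 0.325 with an estimated correlation). In KO against WT, 6736 genes changed (3343 higher, 3393 lower). Without weights or those 4 libraries limma called 6077 (3014 higher, 3063 lower), 6045 of them in both fits. The unweighted fit of 47 libraries called 4661.

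After myelin the KO values were -9.84 ± 0.19 for Apoe, -4.36 ± 0.51 for Col3a1, -3.58 ± 0.16 for Pdgfrb, -3.35 ± 0.20 for Ptgs2, 1.13 ± 0.10 for Lipa and 2.21 ± 0.13 for Lpl. Among fibroblast markers, 16 of 16 fell, and adjusted over the list alone 16 fell (adjusted p = 1.85e-13, adjusted p = 0.220 with an estimated correlation). Among lysosomal genes 33 of 36 rose, with 3 not called, and adjusted over the list alone 33 rose (adjusted p = 1.07e-09, adjusted p = 0.246 with an estimated correlation). In the sterol list 17 of 23 rose, with 6 not called, and adjusted over the list alone 17 rose (adjusted p = 0.00343, adjusted p = 0.379 with an estimated correlation). A member was Msmo1 at 0.65 ± 0.11. Beside these, 10 of 18 astrocyte markers fell, 4 of 5 neuron markers fell and 1 rose and 3 fell of 4 endothelial markers (adjusted over the list alone 12 fell, 4 fell and 1 rose while 3 fell, adjusted p = 0.0168, 0.0144 and 0.0442, and adjusted p = 0.515, 0.245 and 0.220 with an estimated correlation, in turn). With myelin in both, 5850 genes changed (3074 higher, 2776 lower). The reduced count was 5964 (3150 higher, 2814 lower), 5603 of them in both fits. Unweighted, the 47 libraries gave 4350. Both states shared 2395 higher and 2361 lower genes, where independent lists would share 941 and 862. The list calls of both KO comparisons with WT were lost with an estimated correlation.

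Untreated Het libraries also lay far from WT, although their Apoe did not differ from it beyond the spread. Scand1 (4.49 ± 0.31), Lamp1 (2.20 ± 0.27) and the cystatin Cst7 (1.46 ± 0.13) were higher, and Pdgfrb (-3.25 ± 0.19) and Rrm2 (-2.83 ± 0.18) were lower. Among fibroblast markers, 16 of 16 fell, and adjusted over the list alone 16 fell (adjusted p = 3.38e-10, adjusted p = 0.418 with an estimated correlation). Among cell cycle genes 1 of 32 rose and 30 fell, with 1 not called, and adjusted over the list alone 1 rose and 30 fell (adjusted p = 7.43e-15, adjusted p = 0.220 with an estimated correlation). Beside them, 5 of 8 border macrophage markers fell (adjusted over the list alone 5 fell, adjusted p = 0.0190, and adjusted p = 0.418 with an estimated correlation). The coding share was 10.7 ± 7.68% in Het and 23.2 ± 2.54% in WT libraries (SD, n = 5 each). In Het against WT, 6239 genes changed (2837 higher, 3402 lower), or 2188 higher and 4308 lower when scaled to the coding total, which shifted the median of all genes by -0.12. With no filter on low values the balance turned to 5400 higher and 3547 lower, with 5361 genes shared and a shift of that median by 0.12. Divisions of the untreated Het libraries among themselves called up to 6530 genes. In the reduced fit limma called 6041 (2809 higher, 3232 lower), 5768 of them in both fits. The 47 libraries without weights gave 6665. Single libraries moved the count between 3231 genes without Het untreated replicate 1 and 7132 without Het untreated replicate 2.

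KO against Het compared cells of 1 mouse line. KO cells had less Apoe (-9.38 ± 0.21), and less of its neighbour Apoc2 (-2.35 ± 0.17, chromosome 7 from 19671579 to 19677941), which held 171 ± 22.4 scaled TPM in WT, 145 ± 29.8 in Het, 27.0 ± 4.89 in KO, 14.8 ± 1.78 in E4 (SD, n = 5 each) and 6.94 ± 0.494 in E3 libraries (SD, n = 4). Inflammatory genes were lower in KO, where 1 of 26 rose and 16 fell, with 9 not called, and adjusted over the list alone 1 rose and 18 fell (adjusted p = 2.99e-22, adjusted p = 7.86e-04 with an estimated correlation). Examples were Tnf at -2.27 ± 0.14 and Cxcl2 at -1.85 ± 0.17. Immediate early genes were also lower, where 9 of 19 fell, with 10 not called, and adjusted over the list alone 11 fell (adjusted p = 2.14e-13, adjusted p = 0.00660 with an estimated correlation). Its members included Egr1 at -2.47 ± 0.24 and Ier2 at -1.73 ± 0.15. Alternative activation genes were higher, where 3 of 7 rose, with 4 not called, and adjusted over the list alone 4 rose (adjusted p = 0.00991, adjusted p = 0.0447 with an estimated correlation). Of these genes, the complement receptor Vsig4 at 2.05 ± 0.23 and the mannose receptor Mrc1 at 0.74 ± 0.12 were examples. The border macrophage marker Folr2 was higher (2.05 ± 0.15), and in the list of these markers 3 of 8 rose, with 5 not called, and adjusted over the list alone 3 rose (adjusted p = 0.0187, adjusted p = 0.388 with an estimated correlation). The 3 lists of inflammatory, immediate early and alternative activation genes kept their calls with an estimated correlation. Mitochondrially encoded genes held 2.84 ± 0.805% of coding TPM in untreated Het and 1.71 ± 0.221% in untreated KO libraries, with no overlap between them, and the coding share was 10.7 ± 7.68% and 20.8 ± 3.39% (SD, n = 5 each). Of other cells, 6 rose and 1 fell of 18 astrocyte markers (adjusted over the list alone 9 rose while 1 fell, adjusted p = 0.00187, and adjusted p = 0.390 with an estimated correlation). Among fatty acid oxidation and PPAR targets, 8 of 20 rose and 3 fell, with 9 not called, and adjusted over the list alone 10 rose and 3 fell (adjusted p = 0.0405, adjusted p = 0.391 with an estimated correlation). The list held the scavenger receptor Cd36 at 1.42 ± 0.19. Limma called 1788 genes changed (1241 higher, 547 lower), or 2559 higher and 370 lower when scaled to the coding total, which shifted the median of all genes by 0.11. With no filter on low values the balance turned to 516 higher and 914 lower, with 730 genes shared and a shift of that median by -0.11. The reduced fit called 1208 (778 higher, 430 lower), 1137 of them in both fits. The unweighted fit of 47 libraries called 4251. Single removals gave between 63 genes without Het untreated replicate 1 and 4106 without Het untreated replicate 2, and the former were 33 higher and 30 lower.

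Against WT, both knock-in groups were high in astrocyte markers. In E3, 17 of 18 rose, with 1 not called, and adjusted over the list alone 17 rose (adjusted p = 1.75e-14, adjusted p = 0.0528 with an estimated correlation). In E4, 17 of 18 rose, with 1 not called, and adjusted over the list alone 17 rose (adjusted p = 1.69e-15, adjusted p = 0.0460 with an estimated correlation). Mlc1, of astrocyte endfeet, was higher by 3.70 ± 0.14 and 4.47 ± 0.14, the glutamate transporter Slc1a3 by 3.59 ± 0.16 in E3 and Gfap, the intermediate filament of astrocytes, by 4.77 ± 0.20 in E4. Among neuron markers, 5 of 5 rose, and adjusted over the list alone 5 rose (adjusted p = 2.76e-04, adjusted p = 0.0528 with an estimated correlation) in E3, and 5 of 5 rose, and adjusted over the list alone 5 rose (adjusted p = 1.73e-04, adjusted p = 0.0466 with an estimated correlation) in E4. Among border macrophage markers, 6 of 8 fell, with 2 not called, and adjusted over the list alone 6 fell (adjusted p = 2.76e-04, adjusted p = 0.0585 with an estimated correlation) in E3, with Mrc1 at -2.53 ± 0.09 and Ccr1 at -3.26 ± 0.12, and Ccr1 was at -3.48 ± 0.12 in E4. Among complement genes, 2 of 12 rose and 9 fell, with 1 not called, and adjusted over the list alone 2 rose and 9 fell (adjusted p = 0.00548, adjusted p = 0.345 with an estimated correlation) in E3, with C5ar1 at -2.25 ± 0.12. Among phagocytosis receptors 5 of 26 rose and 15 fell, with 6 not called, and adjusted over the list alone 5 rose and 15 fell (adjusted p = 0.00548, adjusted p = 0.406 with an estimated correlation). Among fatty acid synthesis genes 9 of 16 rose and 2 fell, with 5 not called, and adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.0318, adjusted p = 0.406 with an estimated correlation). Ttr (5.84 ± 0.79) and Apoc2 (-4.45 ± 0.13) differed in E3, and Igf2 (-5.85 ± 0.45), Mmp3 (-5.07 ± 0.31) and Rrm1 (-1.16 ± 0.09) in E4. Beside them in E4, 1 rose and 14 fell of 16 fibroblast markers and 1 rose and 7 fell of 8 border macrophage markers (adjusted over the list alone 1 rose while 15 fell and 1 rose while 7 fell, adjusted p = 0.00187 and 8.18e-04, and adjusted p = 0.575 and 0.104 with an estimated correlation, in turn). The coding share was 13.6 ± 2.33% in E3 and 12.1 ± 3.24% in E4 against 23.2 ± 2.54% in WT, and mitochondrially encoded genes held 2.42 ± 0.110%, 2.06 ± 0.149% and 2.00 ± 0.184% of coding TPM (SD, n = 4 to 5). Reads on Apoe were at -9.11 ± 0.17 and -8.44 ± 0.16. In E3 against WT, 6710 genes changed (3228 higher, 3482 lower). The balance turned to 3605 higher and 3033 lower when scaled to the coding total and to 4708 higher and 3777 lower with no filter on low values. Without weights or those 4 libraries limma called 5975 (2787 higher, 3188 lower), 5938 of them in both fits. Unweighted, the 47 libraries gave 4228. In E4 against WT, 7259 genes changed (3488 higher, 3771 lower). It turned to 3891 higher and 3398 lower and to 5440 higher and 4404 lower in the same settings. The reduced count was 6886 (3242 higher, 3644 lower), 6727 of them in both fits. The 47 libraries without weights gave 5492.

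Markers of other cell types thus split the genotypes in untreated cultures. The mean log2 level of astrocyte markers was 2.72 ± 0.10 in WT, 5.09 ± 0.11 in E3, 6.03 ± 0.29 in E4, 2.26 ± 0.48 in Het and 2.61 ± 0.12 in KO (SD, n = 4 to 5). That of fibroblast and pericyte markers was 6.45 ± 0.18, 5.99 ± 0.18, 5.04 ± 0.20, 3.31 ± 0.33 and 3.69 ± 1.03 in the same order. WT, E3, E4 and the Apoe-disrupted line come from different stocks, so genotype and line cannot be told apart in the comparisons between them.

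**Figure D3:**
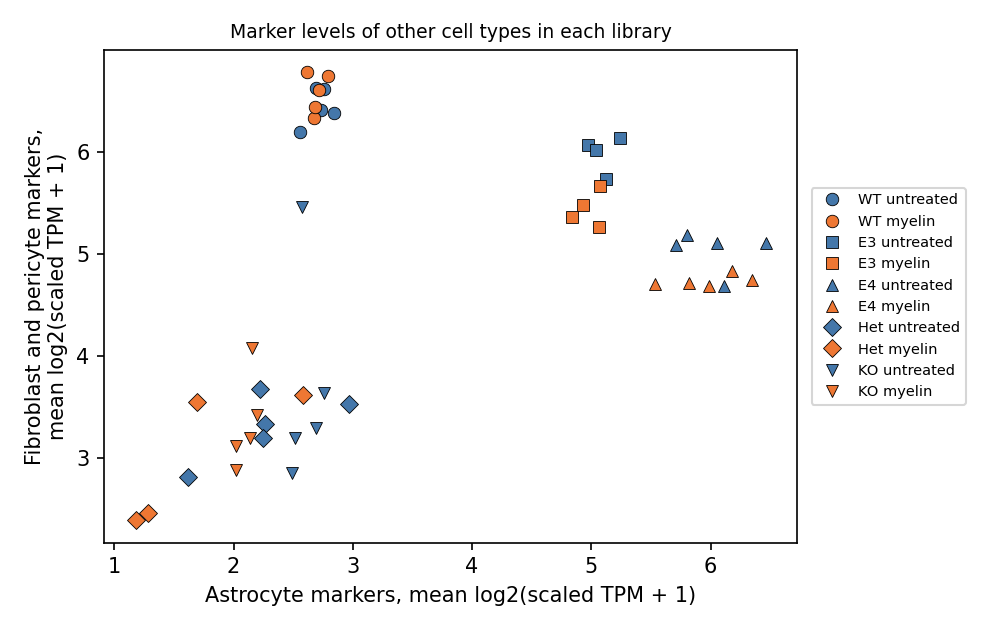
Mean log2(scaled TPM + 1) of astrocyte markers (horizontal axis) and of fibroblast and pericyte markers (vertical axis) in each of the 47 libraries, with genotype as symbol and treatment as colour. Untreated WT libraries averaged 6.45 for fibroblast markers, and untreated E4 libraries averaged 6.03 for astrocyte markers.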

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

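The tests of cell composition, GC content, fibroblasts, line, coding content and the first exchange score were chosen after the result was seen, as were the measures searched for libraries that stand apart, the E3 to WT and E4 to WT interactions the splits with genotype levels removed and the use of divisions within groups. The search covered 7 measures in 10 groups, and 6 of 70 group tests had a library apart from its group, where chance gives about 1 in 20. Apoc2 was apart in E3 untreated replicate 4 (6.21 scaled TPM) and Het untreated replicate 3 (198 scaled TPM). Abcg1 was apart in E4 myelin replicate 4 (35.3 scaled TPM) and Het untreated replicate 2 (24.3 scaled TPM), and Il18bp in Het untreated replicate 2 (16.4 scaled TPM). The mean log2 level of fibroblast and pericyte markers was apart in E4 untreated replicate 5 (4.69). Outside the tested genes, Gm23935 held 80.9% of TPM on average over the 47 libraries, with no control sample to set it against. The myelin response differed between genotypes by an interaction term for 1142 genes in KO against WT, 1046 in E3 against WT and 972 in E4 against WT. These counts fell to 10, 1 and 9 in the unweighted limma fit of 47 libraries and to 385, 233 and 505 in the reduced fit. The 40 genes called in E4 against E3 fell to 0 in both, with 143 and 469 at an unadjusted p under 0.05.

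Other splits of the same libraries were fitted to see whether chance could be excluded. It was excluded by 1 of 100 splits in the mean myelin response (2625 genes, 1172 as the highest other). The same held in the E4 response (2430, 1961) and the KO response (569, 231). It also held in E4 against E3 untreated (2891, 2887) and after myelin (2970, 2654). In the E3 response chance was excluded by 1 of 35 splits (1901, 1537). In the WT response 3 of 100 splits called as many genes (1074, 1281). Chance is left open for it, since the reduced fit called 744 genes, and up to 806 within the WT myelin group alone. The untreated comparisons of KO, E3 and E4 with WT gave 1 of 100 splits each. Their counts were 6736 (6543 as the highest other), 6710 (6609) and 7259 (7256). The medians of the other counts were 5755, 5307 and 6493, so most splits kept a difference between genotypes and these splits are not used to exclude chance. Other values exclude it, and in untreated E4 against E3 as well, since divisions within the untreated WT, KO, E3 and E4 groups, into smaller parts, called at most 251, 58, 1 and 69 genes. In KO against Het as many genes were called in 1 of 100 splits, with 1788 genes and 1546 as the highest other. Chance is left open there, because divisions of the untreated Het libraries among themselves called up to 6530 genes and 63 genes were called without Het untreated replicate 1.

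Chance could not be excluded by these splits alone for the results that follow. As many genes were called in 23 of 100 splits in the Het response (653 genes, 1879 as the highest other). They were called in 5 in KO against WT after myelin (5850, 5980) and 8 in Het against WT (6239, 7228). Some splits of Het called several times the real count, which points to a structure of the samples, with libraries of unequal content. In KO against WT after myelin other values exclude chance, since divisions within the WT and KO myelin groups called at most 622 and 65 genes, and the untreated comparison of other libraries shared 2395 higher and 2361 lower genes, where independent lists would share 941 and 862. In Het against WT other values exclude it too, since over the 10920 tested genes other than Apoe the Het change followed that of KO with a slope of 0.894 (0.841 to 0.957) and a mean r of 0.887 across genes, which are not independent replicates, over 10 divisions of the WT libraries that shared none. That slope and r were computed after the result was seen.

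The same splits say nothing about chance in the interactions, because they mix genotypes, so that differences between genotypes set the outcome. As many genes were called in 23 of 100 splits in the E4 to E3 interaction (40 genes, 3469 as the highest other). In the KO, E3 and E4 to WT interactions they were called in 54 (1142, 7093), 44 (1046, 7018) and 56 (972, 7537). Counts several times the real one point to this structure of the samples. With each gene's level per genotype removed first, 1 of 100 splits called as many genes in the KO, E3 and E4 to WT interactions. Their counts were 1142, 1047 and 972, with 661, 646 and 894 as the highest others. Chance is left open for them, since the reduced fit called 385, 233 and 505 genes, and up to 806 within the WT myelin group alone. Removal of the levels moved the E3 to WT count by 1 gene. The same test gave 4 of 100 splits, with 40 genes and 1801 as the highest other, in the E4 to E3 interaction. Chance is left open for that count, since other splits called several times as many genes and no call was left without weights.

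Untreated E4 libraries had more inflammatory and astrocyte RNA and less fibroblast RNA than E3. A lower share of microglia would raise both other cell types, but the medians of astrocyte and fibroblast markers lay 1.84 log2 units apart with opposite signs, and after a GC content and length correction the inflammatory list had an adjusted p of 1.11e-09. Whether astrocyte RNA carries the inflammatory genes stays open, since within groups, r was 0.0792 (permutation p = 0.784) and rho 0.00929 (permutation p = 0.976) over 18 libraries, and r was -0.0356 without the 2 libraries farthest from the median. This was the 1 relation across libraries computed, so its adjusted p is the same. An effect of the APOE allele remains a hypothesis and cannot be told apart from more astrocytes, a lower share of microglia or the line of mice.

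Untreated replicate 2 of Het stood at the level of myelin-treated libraries and its myelin counterpart at the untreated level, and an exchange of the 2 libraries is a candidate explanation. On genes of the KO response the untreated library scored 0.472 above the myelin library, where the other Het libraries had a gap of 0.410 in the labelled direction, and on genes shared by the E3 and E4 responses it scored 0.397 above it, with a gap of 0.263 in the others. Low coding content is argued against for the untreated library, which held 18.4% coding TPM, and stays open for the myelin library, which held 2.91%, below the other myelin Het libraries. No biological explanation was tested, and the libraries were kept as labelled.

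KO and Het libraries both lay far from WT. A linear dose of Apoe is argued against by a slope of the Het on the KO change of 0.904 (0.850 to 0.966 over 10 divisions of the WT libraries, so that the sides shared none, 6735 genes), although Het Apoe itself did not differ from WT beyond the spread. A GC content and length trend is argued against by 6820 genes called after correction, and fewer fibroblasts as the whole cause by 1021 genes called over 2-fold higher in KO. Line, stock or preparation cannot be told apart from genotype, as they split the libraries alike. The 1788 genes called between KO and Het of 1 line are uncertain. They were 63 without Het untreated replicate 1, and divisions within untreated Het called up to 6530. Untreated Het held 47337 scaled TPM of Apoe and KO 74.6, so changes that Het shares argue against loss of Apoe. It stays open for the rest.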

How the results depend on the processing

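All counts here are genes called by limma, and the cause of each change was not tested unless given. The unweighted fits, pseudocounts of 0.1 and 5, coding-total scaling, the GC and length correction and the fits without Het libraries were chosen after seeing the data. The planned count-based models, limma-voom included, were not run, because TPM are not counts. Counts not listed stayed within 1.5 times. The Apoe difference of Het against WT was -0.15 without the 4 Het libraries of low coding content, against -0.43. The unweighted fit gave 1240 in the mean myelin response, 419 in the WT response, 25 in the E3 response, 329 in the E4 response, 136 in the Het response, 13 in the KO response, 739 in E4 against E3 untreated, 518 in E4 against E3 after myelin, 0 in the E4 to E3 interaction (143 at an unadjusted p under 0.05), 10 in the KO to WT interaction, 4251 in KO against Het, 4228 in E3 against WT, 1 in the E3 to WT interaction and 9 in the E4 to WT interaction. Without the 4 Het libraries of low coding content as well, it gave 699 in the E3 response, 1357 in the E4 response, 2 in the Het response, 254 in the KO response, 1918 in E4 against E3 untreated, 1257 in E4 against E3 after myelin, 0 in the E4 to E3 interaction (469 at an unadjusted p under 0.05), 385 in the KO to WT interaction, 233 in the E3 to WT interaction and 505 in the E4 to WT interaction. Removing those 4 from the weighted fit gave 0 in the Het response (667 at an unadjusted p under 0.05), and removing both Het replicates numbered 2 gave 4130 in KO against Het. With no filter on low values it came to 1383 in the mean myelin response, 909 in the E3 response, 104 in the Het response, 347 in the KO response, 2 in the E4 to E3 interaction, 693 in the KO to WT interaction and 394 in the E3 to WT interaction, and with a stricter one to 1099 in the Het response and 86 in the E4 to E3 interaction. Fitting only the groups compared gave 349 in the WT response, 0 in the Het response (1477 at an unadjusted p under 0.05), 0 in the E4 to E3 interaction (1366 at an unadjusted p under 0.05) and 628 in the E3 to WT interaction. Pseudocount 5 gave 1085 in the Het response, coding-total scaling 1567 in the Het response and 2929 in KO against Het and the GC and length correction 21 in the E4 to E3 interaction and 617 in the E3 to WT interaction. With an estimated correlation 11 of 189 list calls held in the 16 planned comparisons. Set against the other genes, the direction of MHC class I genes in the Het response turned with no filter, although their median stayed above 0 at 0.14. The median of ER stress genes in KO against Het turned to 0.18 unweighted. Some further balances near even turned, as in the E4 response with the replicate block (1322 higher, 1361 lower), in E4 against E3 untreated unweighted (358 higher, 381 lower) and with no filter in KO against WT untreated (4148 higher, 4048 lower) and after myelin (3451 higher, 3682 lower).

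With the replicate number as a block, limma gave 373 in the Het response, 350 in the KO response, 0 in the E4 to E3 interaction (1034 at an unadjusted p under 0.05) and 670 in the KO to WT interaction, and no other count moved by over 1.5 times. The numbers do not pair the libraries, since 5 of 23 same-numbered pairs correlated over 0.1 (range -0.538 to 0.455), and 3 correlated best with their own number.

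Leaving out 1 library at a time gave 1108 to 3173 in the mean myelin response, 857 to 2392 in the WT response, 578 to 2416 in the E3 response, 1028 to 3027 in the E4 response, 0 to 3021 in the Het response, 335 to 657 in the KO response, 2364 to 2893 in E4 against E3 untreated, 1151 to 3410 in E4 against E3 after myelin, 1 to 84 in the E4 to E3 interaction, 6375 to 6656 in KO against WT untreated, 5504 to 6286 in KO against WT after myelin, 819 to 2379 in the KO to WT interaction, 3231 to 7132 in Het against WT, 63 to 4106 in KO against Het, 6223 to 6665 in E3 against WT, 6626 to 7273 in E4 against WT, 312 to 2448 in the E3 to WT interaction and 581 to 2210 in the E4 to WT interaction. Apoe ranged from 0.60 to 0.77 in E4 against E3, -0.64 to -0.02 in Het and -9.61 to -9.49 in KO. List medians that turned, in the Het response, ranged from -0.14 to 0.24 for MHC class I, -0.17 to 0.99 for interferon, -0.69 to 0.0147 for cell cycle and -1.13 to 0.0752 for fibroblast genes. The mean myelin response came to 1108 without Het untreated replicate 1, 1213 without Het myelin replicate 1 and 1271 without Het myelin replicate 3. The WT response came to 2392 without WT myelin replicate 4. The E3 response came to 1162 without E3 untreated replicate 2, 1192 without E3 myelin replicate 3 and 578 without E3 myelin replicate 4. The E4 response came to 1503 without E4 untreated replicate 2, 1028 without E4 untreated replicate 3 and 1548 without E4 myelin replicate 3. Without untreated replicates 1 to 4 in turn, the Het response came to 0 (301 unadjusted), 1094, 1314 and 3021. Without myelin replicates 1 to 4 it came to 0 (153 unadjusted), 119, 0 (637 unadjusted) and 372. The KO response came to 371 without KO myelin replicate 1 and 335 without KO untreated replicate 3. E4 against E3 after myelin came to 1151 without E3 myelin replicate 4. The E4 to E3 interaction came to 19 without E3 untreated replicate 2, 3 without E3 untreated replicate 4, 8 without E3 myelin replicate 1, 84 without E3 myelin replicate 2, 1 without E3 myelin replicate 4, 5 without E4 untreated replicate 2, 5 without E4 untreated replicate 3, 71 without E4 untreated replicate 5, 80 without E4 myelin replicate 1, 17 without E4 myelin replicate 2, 9 without E4 myelin replicate 3 and 61 without E4 myelin replicate 5. The KO to WT interaction came to 2379 without WT myelin replicate 4. Het against WT came to 3231 without Het untreated replicate 1. KO against Het came to 63 without Het untreated replicate 1, 4106 without Het untreated replicate 2 and 3258 without Het untreated replicate 4. The E3 to WT interaction came to 652 without WT untreated replicate 4, 539 without WT untreated replicate 5, 613 without WT myelin replicate 3, 2448 without WT myelin replicate 4, 652 without WT myelin replicate 1, 633 without E3 untreated replicate 2, 685 without E3 myelin replicate 3 and 312 without E3 myelin replicate 4. The E4 to WT interaction came to 614 without WT untreated replicate 5, 2210 without WT myelin replicate 4 and 581 without E4 untreated replicate 3. Of named genes, 73 of 2142 values lost their call under the settings and 40 of 2206 without a library, and none reversed. Of list tests, 166 of 2779 and 180 of 3056 lost theirs.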

Other observations

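The window around Apoe was set before any result for its neighbours was seen. Predictions for 3 comparisons were written after the low Apoc2 of the altered lines had been seen, and before the tests below were run. The other comparisons had no written prediction. The altered gene lies on chromosome 7, and a hypothesis is that donor strain sequence around Apoe may change nearby genes. It was tested for 151 genes within 10.0 Mb of Apoe with Fisher's exact test, two-sided, in 16 comparisons. The odds ratio of a call was 1.14 in untreated E4 against E3 (exact p = 0.458, adjusted p = 0.666), 1.07 in E3 against WT (exact p = 0.737, adjusted p = 0.842) and 1.014 in KO against Het (exact p = 0.912, adjusted p = 0.973). No excess of calls was detected in these 3 comparisons, for which the hypothesis had been written. A test of call rates cannot show large changes of single genes, least of all in E3 against WT, where 61.4% of the genes outside the window were called. Within the window, chosen after their values were seen, Tmem160 stood against WT at 4.27 ± 0.16 in KO, 4.17 ± 0.22 in Het, 2.85 ± 0.17 in E3 and 3.44 ± 0.17 in E4, and Apoc2 at -2.69 ± 0.13 in KO, -4.45 ± 0.13 in E3 and -3.39 ± 0.13 in E4, and, not called, -0.33 ± 0.17 in Het (log2 fold change ± SE). KO against Het was -2.35 ± 0.17 for Apoc2 and 0.11 ± 0.22 for Tmem160, which was not called there. The hypothesis stays open for single genes. Elsewhere 4 of the 16 comparisons had an excess at the same adjusted p of 0.0279. The odds ratios were 1.62 in the mean myelin response, 1.93 in the WT response, 1.69 in the E4 response and 1.89 in the KO to WT interaction. The WT response compares libraries that carry no altered Apoe, so donor sequence cannot account for the excess there. Genes of 1 region are not independent, and the cause was not tested.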
